A study of Mus musculus and unidentified plasmid with 6 samples.

How the data were processed

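Guide RNA sequences were read from the plasmid pool and from genomic DNA of 5 cell populations of the mouse line Hoxb8-FL transduced with the Brie library. Per the labels, 110000000 cells were transduced to reach about 400 cells per guide, 50000000 progenitors were taken on day 5 and again on day 11 after selection, 100000000 differentiated cells were taken before sorting, and the sorts gave 4600000 cDC2 and 3000000 pDC. The libraries were amplified following the library depositor's sequencing protocol, per the labels. The authors deposited 1 table of raw read counts per guide sequence, with no normalization, as its whole numbers and unequal column totals show. The tool that assigned reads to guides is not given in the sources used here. The submitters' processing notes name the genome build mm10, but the table holds no coordinates and none are given here. Columns were assigned to groups by the names that the labels give them, and each group had 1 library.

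The tests planned before the data were examined worked on genes and on fixed lists of genes, by rank aggregation of the guides of each gene centred on non-targeting guides. They could not be run, because the table pairs no guide with a gene and marks no non-targeting guide, and a genome or a table of guide targets was not used here. The planned rule for named genes (the 10 with lowest p in each direction, list members and fixed genes) had no genes to apply to. Guides were analysed instead, and the guide pairs, their tests and the rule for naming guides were chosen after seeing the data. The rule takes the pair with the lowest and the pair with the highest value of its weaker guide in a comparison, names the one with the smaller p (both for pDC against cDC2), and, chosen by reads, the guides with most reads in bulk DC.

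Counts were scaled to a library total of 1000000 (RPM), 1 RPM was added, and the log2 ratio of 2 libraries was centred on the median over guides. On this scale the change of a guide with few reads is understated. Guides with fewer pDNA reads than 10% of the median (44.6 reads) were left out, which removed 536 of 79633 guides and kept 79097. Before centring, the median log2 ratio was 0.02 for day 5 against pDNA, -0.34 for day 11 against pDNA, -0.36 for day 11 against day 5, -0.60 for bulk DC against day 11, -0.08 for cDC2 and -0.07 for pDC against bulk DC, and 0.01 for pDC against cDC2, so changes are relative to the median guide. Guides at least 2-fold lower or higher were counted. The spread of each comparison was measured as a robust SD, the scaled median absolute deviation, which was 0.41, 0.80, 0.61, 0.67, 0.68, 0.75 and 0.98 in the same order. Sampling of reads alone gave an SD of 0.10, 0.10, 0.11, 0.10, 0.13, 0.11 and 0.14 for the median guide, well below the observed spread. Single guides have no test against this spread.

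Guides whose 20-base sequences overlap by at least 16 bases, on the same or on opposite strands, were taken to cut at nearly the same place. The table held 547 such pairs, where 3.92 would arise by chance from random sequence, and 453 pairs that share no guide and passed the filter were used, 266 on the same strand and 187 on opposite strands. Partners' log2 changes were compared by Pearson's r and Spearman's rho with each pair entered in both orders. Two-sided permutation tests shuffled partners 100000 times, so that 1e-05 is the smallest unadjusted p possible, and p was adjusted by Benjamini-Hochberg over the 7 comparisons, with 95% intervals from 10000 bootstrap draws of pairs. Counts of pairs changed in the same direction, and the lowest and highest pair, were compared one-sided with 10000 random pairings of the same guides, and each kind was adjusted by Benjamini-Hochberg over its 14 tests. An adjusted p of 0.0007 for such a count comes from the smallest p that 10000 pairings can give. These correlations run across guides, which are not independent replicates. Guides in pairs are not a random sample of the library, and the pair correlation of log2 pDNA reads was 0.11. Ratios of single guides have exact binomial intervals, and shares have Wilson intervals, at the 95% level.

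Reads of a guide in pDNA above the median guide, as a share of its reads in the other 5 libraries, were summed over the 12 guides with most bulk DC reads and gave 0.717%. Subtracting this share from every library sets 10056 guides to 0 in cDC2 and 6078 in pDC, against at most 750 in any other library, so it is a rough correction for the sorted libraries. Alternatives were TMM factors from edgeR 4.0.16 in R 4.3.3, pseudocounts of 5 and 0.1 RPM, no filter or a filter at 50% of the median pDNA reads (223 reads), other reference libraries, subtraction of that 0.717% from every library, guides with 6 to 14 G or C bases, removal of the 100 guides with most bulk DC reads, and narrower sets of pairs. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The method was tested on simulated data, with counts drawn from the 79097 guides, 200 of them changed and the spread put in equal to the observed one, which came back smaller (0.74 for 0.80 in day 11 against pDNA, 0.65 for 0.98 in pDC against cDC2). For bulk DC against day 11, 74% of guides lowered by 2 log2 units were at least 2-fold lower, 92% of those raised by 2 were at least 2-fold higher, and 4.15% and 4.54% of unchanged guides also passed. For day 5 against pDNA the shares were 96% and 98%, with 0.463% and 0.633% of unchanged guides. Unchanged guides came out at least 2-fold lower and higher in 7.61% and 9.15% for day 11 against pDNA, 3.25% and 3.91% for day 11 against day 5, 3.56% and 3.44% for cDC2 and 4.41% and 5.77% for pDC against bulk DC, and 9.61% and 7.89% for pDC against cDC2. The simulated spread was below the observed one in every comparison (0.51 for 0.68 in cDC2 and 0.56 for 0.75 in pDC, against bulk DC). The simulation took the whole observed spread as that of unchanged guides, whose own spread is not known without replicates or marked non-targeting guides. If that holds, these shares understate how many unchanged guides would pass in the data. If part of the spread comes from effects of guides, they can overstate it. An observed count above or below them therefore does not by itself show or exclude an excess. Paired guides were given, on top of that spread, a change shared by both partners with the same SD. A pair correlation of 0.46 put into the simulated bulk DC comparison was recovered as 0.42, and one of 0.49 in pDC against cDC2 as 0.38, so a correlation of that size is understated. Because every simulated pair shared a large change, this does not measure how well small or rare shared changes are detected.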

Results

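The screen followed CRISPR guides through the differentiation of Hoxb8-FL cells, a mouse bone marrow-derived progenitor line kept immature by an estrogen-dependent Hoxb8 transgene and grown with Flt3 ligand, which gives rise to dendritic cells once Hoxb8 is switched off. Cells carrying Cas9 received the genome-wide Brie library, in which each lentivirus encodes 1 guide RNA of 20 bases, and the guides were counted by sequencing. Each of 6 groups was represented by 1 library. These were the plasmid pool (pDNA), progenitors on day 5 and day 11 after selection, unsorted dendritic cells on day 18 (bulk DC), and 2 populations sorted from them. The sorted conventional type 2 dendritic cells (cDC2) were CD11c+ CD11b+ B220-, and the sorted plasmacytoid dendritic cells (pDC) were CD11c+ CD11b- B220+. Total reads were 36940822 in pDNA, 25255364 on day 5, 31248498 on day 11, 60619045 in bulk DC, 20458401 in cDC2 and 32794347 in pDC. The table listed 79633 guides by sequence without naming their genes, so the results below concern guides and pairs of guides whose target sequences overlap, and Trim33, which the series title names, was not analysed here. With 1 library per group no difference had a replicate check, and every test compares these libraries and not the conditions they stand for. Intervals cover counting error only, because PCR reads are not independent molecules.

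The dendritic cell libraries were dominated by few guides. The guide ACTATTCCAATGTTCAGTGG took 7.99% of all bulk DC reads (95% Wilson interval 7.985 to 7.998), 8.25% in sorted cDC2 (8.24 to 8.26) and 7.03% in sorted pDC (7.02 to 7.04). In progenitors it took 0.296% on day 5 (0.294 to 0.299) and 2.79% on day 11 (2.79 to 2.80), but 0.717% of its reads in the other 5 libraries, the share at which the leading guides appeared in pDNA, came to 93.7% of its day 5 reads. Its log2 change from day 5 to day 11 was 3.59, or 7.46 with that share subtracted from each library. The second value is not well determined, because little of the day 5 count is left and the share varied between guides. The 12 guides with most reads in each library, taken separately, held 1.01% of the reads on day 5, 8.91% on day 11, 30.2% in bulk DC, 30.6% in cDC2 and 23.2% in pDC. The 12 leading guides of bulk DC were also the 12 leading guides of both sorted libraries and of day 5, and 7 of them were among the 12 leading guides of day 11. On day 5 this rank and their summed share are limited by the same 0.717%, which came to between 77.3% and 126% of the day 5 reads of each. They were the 12 leading guides of pDNA too, where each had reads equal, above the median guide, to between 0.648% and 0.802% of its reads in the other 5 libraries.

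**Figure D1:**
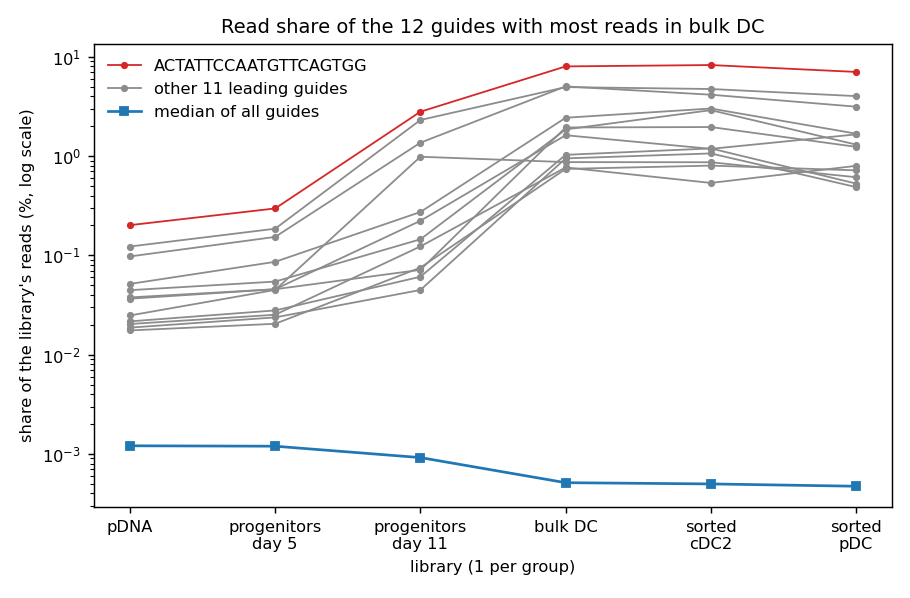
Share of each library's reads, on a log scale in percent, taken by the 12 guides with most bulk DC reads and by the median of all guides, with libraries along the horizontal axis and 1 line per guide. The red line, ACTATTCCAATGTTCAGTGG, goes from 2.79% on day 11 to 7.99% in bulk DC.

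Guide representation became more uneven with each step of the culture. The Gini coefficient, which is 0 when all guides have equal reads, was 0.188 in pDNA, 0.281 on day 5, 0.484 on day 11, 0.701 in bulk DC, 0.727 in cDC2 and 0.726 in pDC. The median guide had 446, 302, 287, 311, 102 and 155 reads in these libraries. Between 85 guides in pDNA (0.107%) and 973 guides in cDC2 (1.22%) had 0 reads, and a count of 0 allows up to 3 reads, or 0.0812 reads per 1000000 (RPM) in pDNA and 0.147 in cDC2. In bulk DC counts of 0 do not measure loss, since 379 of the 384 guides with 0 reads were already scarce in pDNA and were among the 536 left out below. Of the guides with 0 reads in the sorted libraries, 464 of 973 in cDC2 and 436 of 595 in pDC were among those left out. The rest had passed the filter on pDNA reads. In any library, reads counted in the wrong library would give a lost guide reads.

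**Figure D2:**
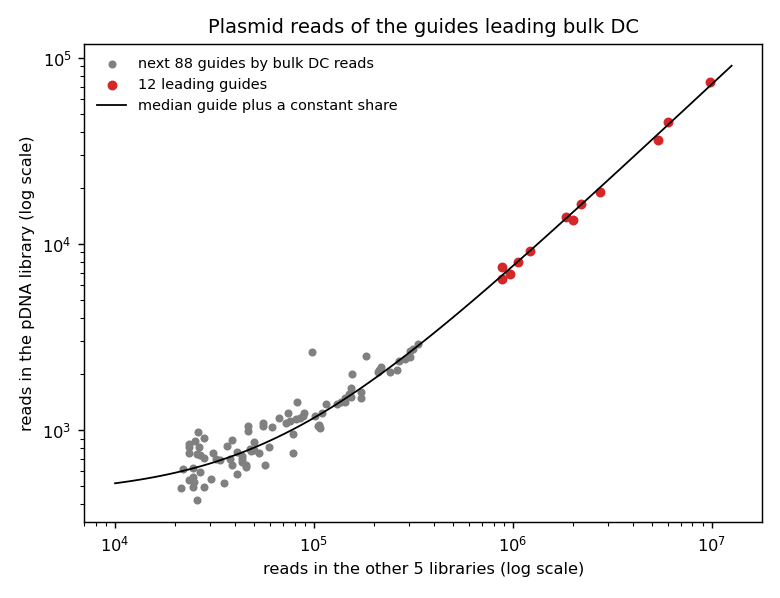
Reads in the pDNA library against reads in the other 5 libraries, both on log scales, for the 100 guides with most bulk DC reads, 1 point per guide. The line is the median guide plus 0.717% of the reads in the other 5 libraries, and the 12 leading guides (red) have shares between 0.648% and 0.802%.

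The first question was which guides were lost while progenitors expanded. By day 5, 6872 of 79097 guides (8.69%) were at least 2-fold lower than in pDNA, relative to the median guide, and 258 (0.326%) were at least 2-fold higher. Losses reached 4-fold for 2008 guides, against 1 guide higher by that much. With a pseudocount of 5 RPM in place of 1, 3711 guides were at least 2-fold lower and 78 higher. Guides with overlapping target sequences were lost together. Among 453 pairs with overlapping target sequences the log2 changes of partners correlated with Pearson's r = 0.62 (95% bootstrap interval 0.56 to 0.68) and Spearman's rho = 0.59, each with an adjusted permutation p of 3.5e-05. Both guides were at least 2-fold lower in 110 pairs, where random pairings of the same guides gave 54.7 (adjusted permutation p = 0.0007). CCTTCTTGGAGCCCTTCTTC, at 516 reads in pDNA and 15 on day 5, was lower by a log2 change of -3.25, and its partner CTTCTTGGAGCCCTTCTTCG, at 696 and 49 reads, by -2.77. A pair this low appeared often in random pairings (permutation p = 0.227, adjusted 0.358 over the 14 lowest and highest pairs), and paired guides were lost more often than others, with 34.8% of them at least 2-fold lower.

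By day 11, before differentiation was induced, the loss had deepened. At least 2-fold lower than in pDNA were 12586 guides (15.9%), of which 5477 were at least 4-fold lower and 1589 at least 8-fold lower. Another 6811 guides (8.61%) were at least 2-fold higher, and 192 at least 8-fold higher. A pseudocount of 5 RPM gave 6246 lower and 3473 higher. In simulated libraries of this comparison 7.61% of unchanged guides came out at least 2-fold lower and 9.15% higher, at a robust SD of 0.74 where the data had 0.80. The simulation took the whole observed spread as that of unchanged guides, so it cannot tell 2-fold gains apart from spread. Beyond 3 robust SD, 357 guides were higher and 3998 lower, where a normal distribution would give 107 on each side. Overlapping guides again changed together, with r = 0.54 (0.47 to 0.60), rho = 0.50 and an adjusted permutation p of 3.5e-05 for each, and 119 pairs had both guides at least 2-fold lower against 71.0 in random pairings (adjusted permutation p = 0.0007). The lowest pair had a permutation p of 0.0303 against random pairings, which did not pass after adjustment (0.141). ATCATGTGGATGAATCTGAT had 907 reads in pDNA and 16 on day 11, a log2 change of -3.74 and a ratio of RPM of 0.0209 (95% exact interval 0.0119 to 0.0341). Its partner ATGTGGATGAATCTGATAGG had 798 and 10 reads, a log2 change of -3.76 and a ratio of 0.0148 (0.00708 to 0.0274). Reads counted in the wrong library could make up part of day 11 counts this low, which these intervals do not cover. No such sharing was seen among gains, since 1 pair had both guides at least 2-fold higher and random pairings gave 1.75.

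**Figure D3:**
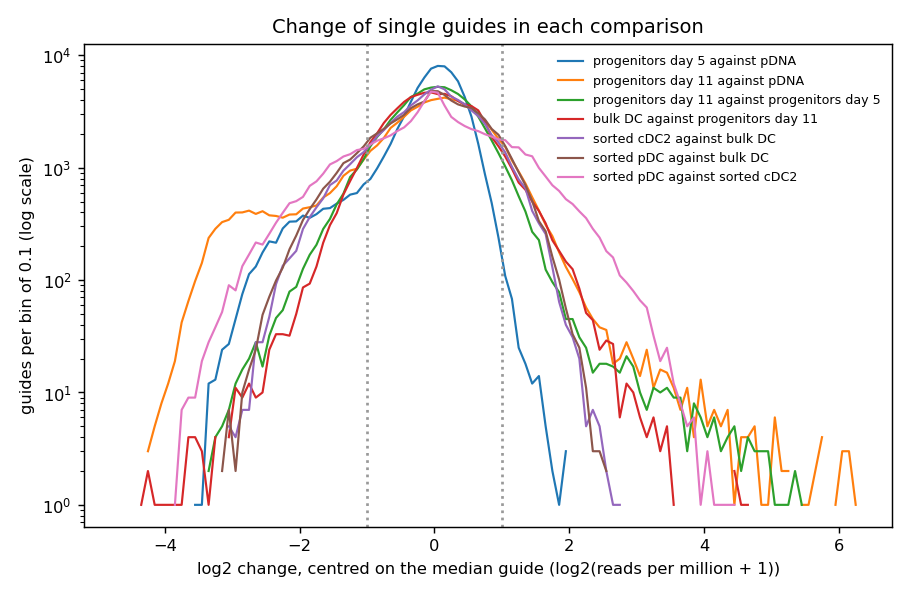
Number of guides per bin of 0.1 log2 units, on a log scale, against the log2 change centred on the median guide, with 1 line for each of the 7 comparisons and dotted lines at 2-fold. The day 5 and day 11 lines against pDNA have a long lower side, with 2008 and 5477 guides at least 4-fold lower, and the line of pDC against cDC2 is wide on both sides.

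Between day 5 and day 11 guides changed in both directions, with a balance that turned with the pseudocount. At least 2-fold lower were 5589 guides (7.07%) and at least 2-fold higher 3953 (5.00%), with 350 guides at least 4-fold higher and 128 at least 8-fold higher. With a pseudocount of 5 RPM, 458 were at least 2-fold lower and 1705 higher, and with 0.1 RPM 9520 and 4912. Single guides past 2-fold were not told apart from the spread, a robust SD of 0.61. Beyond 3 robust SD, 664 guides were lower and 461 higher, where a normal distribution would give 107 on each side. Guides whose overlapping partner had been lost by day 5 went on falling. The 315 such guides changed by a mean log2 of -0.39 (SD 0.64) and the other 591 paired guides by -0.04 (SD 0.65), a difference of -0.35 (95% bootstrap interval -0.45 to -0.26). Their median level went from 12.2 RPM in pDNA to 2.93 on day 5 and 0.960 on day 11, while that of the others went from 12.2 to 10.8 and 7.87. Over all pairs the correlation was low, with r = 0.11 (0.02 to 0.20), rho = 0.11 and adjusted permutation p values of 0.0341 and 0.0299, and it was no longer past the threshold with a pseudocount of 5 RPM (r = 0.0050, adjusted permutation p = 0.916), while with 0.1 RPM it was higher (r = 0.29, adjusted permutation p = 0.00012). The highest pair, CTGTGGTCTGGCAGGACACT with a log2 change of 1.59 and TGGTCTGGCAGGACACTGGG with 1.24, was within what random pairings gave (permutation p = 0.186, adjusted 0.358). The leading guide of day 11 was ACTATTCCAATGTTCAGTGG, and TGTGCATATTTATTGCATCG went from 11320 to 307362 reads, a log2 change of 4.81. With 0.717% of the guide's reads in the other libraries subtracted from each library, that change was 6.91, a value that depends on the exact share.

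The next question was which guides were gained or lost as progenitors became dendritic cells. In bulk DC, 5123 guides (6.48%) were at least 2-fold lower than on day 11 and 5847 (7.39%) at least 2-fold higher, with 450 guides at least 4-fold higher and 252 at least 4-fold lower. With a pseudocount of 5 RPM, 1221 were at least 2-fold lower and 2141 higher. The robust SD was 0.67, so guides past 2-fold were not told apart from spread. Beyond 3 robust SD, 240 guides were lower and 424 higher, where a normal distribution would give 107 on each side. Relative to the median guide, each of the 12 leading guides was higher in bulk DC, by log2 changes from 0.42 to 5.36. With that share subtracted the changes were from 0.42 to 6.83. These guides were chosen by their bulk DC reads, which favours a rise in this comparison. The guide with the change of 0.42 fell from 0.984% of all reads on day 11 to 0.868% in bulk DC, while the others took a larger percentage. Its rise came from centring on a median log2 ratio of -0.60. CGGCACGACTCAGTTCGTCG had the change of 5.36, going from 22312 to 1175760 reads, and 0.717% of its reads in the other 5 libraries came to 64.5% of its day 11 reads. Subtracting that share gave a change of 6.83. The same share came to 126% of this guide's day 5 reads, more than were there, so it is too high for this guide on day 5. The 64.5% and the 6.83 are therefore not well determined. Overlapping guides hardly changed together in this step. Their correlation was r = 0.11 (0.03 to 0.20) and rho = 0.13, with adjusted permutation p values of 0.0341 and 0.0106, and it was not past the threshold with trimmed mean of M values (TMM) scaling (r = 0.067, adjusted permutation p = 0.258). In 2 pairs both guides were at least 2-fold lower and in 2 both at least 2-fold higher, against 0.998 and 1.53 in random pairings (adjusted permutation p = 0.709 for each). The lowest pair, CAATCTGTGAAGTGACAAGG with a log2 change of -1.07 and TATCAATCTGTGAAGTGACA with -1.67, was within what random pairings gave (permutation p = 0.502, adjusted 0.703). Guides whose partner had been lost by day 5 had a mean log2 change of 0.30 and the others 0.02, a difference of 0.28 (0.19 to 0.37), but the levels behind it were a median of 0.960 RPM on day 11 and 0.445 in bulk DC, where the added 1 RPM compresses a loss.

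**Figure D4:**
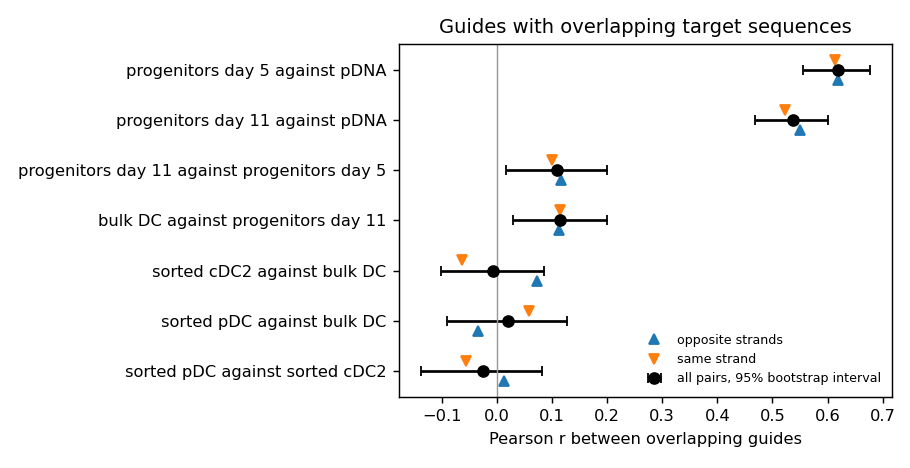
Pearson's r between the log2 changes of 453 pairs of overlapping guides in each of the 7 comparisons, with 95% bootstrap intervals (black) and the values for 266 pairs on the same strand and 187 pairs on opposite strands (triangles). The comparisons with pDNA lie at 0.62 and 0.54, and those of sorted cells have intervals that include 0.

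Many guides were past 2-fold between sorted cDC2 and bulk DC, without overlapping guides moving together. At least 2-fold lower in cDC2 were 8421 guides (10.6%) and at least 2-fold higher 5128 (6.48%), which became 631 and 503 with a pseudocount of 5 RPM. Beyond 3 robust SD, 618 guides were lower and 61 higher, where a normal distribution would give 107 on each side. Single guides past 2-fold were not told apart from the spread, a robust SD of 0.68. Partners correlated with r = -0.01 (-0.10 to 0.09; adjusted permutation p = 0.877) and rho = -0.00095 (adjusted permutation p = 0.984). With day 11 progenitors as the reference, which adds the change up to bulk DC, r was 0.10 (adjusted permutation p = 0.0367). The numbers of pairs with both guides at least 2-fold lower (4, against 3.42 in random pairings) or higher (1, against 1.75) did not pass the test, with adjusted permutation p values of 0.709 and 0.962. The lowest pair was AGGCTGCAGCCACAGCTCTG, with 361 reads in bulk DC and 13 in cDC2, and CAGGCTGCAGCCACAGCTCT, with 181 and 3 reads, whose ratio of RPM was 0.0491 (95% exact interval 0.0100 to 0.146). The interval does not cover reads counted in the wrong library, which could make up part of cDC2 counts this low. Random pairings gave a pair this low with a permutation p of 0.0964 (adjusted 0.270).

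In sorted pDC, 9615 guides (12.2%) were at least 2-fold lower than in bulk DC and 5872 (7.42%) at least 2-fold higher. The excess of lower over higher guides turned with a pseudocount of 5 RPM, which gave 730 lower and 1524 higher. At a robust SD of 0.75, guides past 2-fold were not told apart from spread. By more than 3 robust SD, 334 guides were lower and 14 higher, where a normal distribution would give 107 on each side. Both guides were at least 2-fold higher in 8 pairs, more than the 1.95 that random pairings gave (adjusted permutation p = 0.0014 over 14 counts of pairs). The highest pair was ATGCACCTACAGAATAAGCG, which went from 1130 to 2173 reads with a log2 change of 1.85, and CACCTACAGAATAAGCGTGG, which went from 33 to 126 reads with a log2 change of 1.72. Their ratios of RPM were 3.55 (95% exact interval 3.31 to 3.82) and 7.06 (4.78 to 10.7), and the permutation p of the pair was 0.0231, which did not pass after adjustment (0.141). Over all pairs the correlation was r = 0.02 (-0.09 to 0.13; adjusted permutation p = 0.783) and rho = -0.01 (adjusted permutation p = 0.890). The count did not pass the test with a pseudocount of 5 RPM (1 pair against 0.1002 in random pairings, adjusted permutation p = 0.390), on opposite strands (2 of 187 pairs against 0.683, adjusted permutation p = 0.496) or for pairs with at least 3 RPM in bulk DC (3 of 147 against 0.722, adjusted permutation p = 0.115). Nor did it with day 11 progenitors as the reference (13 pairs against 10.2, adjusted permutation p = 0.615).

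The last comparison set the sorted populations against each other and asked which guides favoured one type of dendritic cell. At least 2-fold lower in pDC than in cDC2 were 13601 guides (17.2%) and at least 2-fold higher 13678 (17.3%), which became 3531 and 4938 with a pseudocount of 5 RPM. The spread between guides was also the largest, with a robust SD of 0.98 where read sampling alone gave 0.14 for the median guide. Guides past 2-fold were therefore not told apart from spread. Beyond 3 robust SD, 286 guides were lower and 269 higher, where a normal distribution would give 107 on each side. Of the 12 leading guides, 2 were higher in pDC and 10 higher in cDC2, with log2 changes from -1.18 to 0.56. The lowest pair in pDC was CAACGTGAGTGAGACCAACC, with 137 reads in cDC2 and 10 in pDC and a log2 change of -2.57, and CTGGTTGGTCTCACTCACGT, with 184 and 11 reads and a change of -2.91, on opposite strands (permutation p = 0.0292, adjusted 0.141). Part of pDC counts this low could be reads counted in the wrong library. The highest pair was CATGGCTATATTGTAAACCA, with 70 reads in cDC2 and 680 in pDC and a log2 change of 2.29, and TGGCTATATTGTAAACCAAG, with 63 and 716 reads and a change of 2.48 (permutation p = 0.0592, adjusted 0.207). Partners did not correlate detectably, with r = -0.03 (-0.14 to 0.08; adjusted permutation p = 0.783) and rho = -0.04 (adjusted permutation p = 0.487).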

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

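All tests in this part were chosen after the results they measure had been seen.

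Some of the guides left out for scarce pDNA reads had reads in cells. Of the 536 guides left out, whose highest pDNA count was 43, 25 had more bulk DC reads than that, while 379 had 0 bulk DC reads. These are raw counts, not scaled to the larger total of the bulk DC library. The highest was TCTCACTGTAGACCGCGTAG, with 24 reads in pDNA, 48 on day 5, 135 on day 11 and 932 in bulk DC, where the median guide had 311.

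Scarcity in pDNA followed the first bases of the guide. Of 516 guides that begin with TCTC or AGACG or hold CGTCTC or GAGACG, 97.5% (95% Wilson interval 95.7 to 98.5) had under 10% of the median pDNA reads, against 0.0417% (0.0297 to 0.0586) of the other 79117. TCTC was first of 255 starts of 4 bases, with the next at 21.9%. With starts in TCTC left out, AGACG was first of 987 starts of 5 bases, with the next at 4.76%. A candidate explanation is a BsmBI recognition site (CGTCTC, or GAGACG on the other strand) completed by vector bases next to the guide and cut during cloning. The vector sequence was not examined and no biological explanation was tested.

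The 12 guides leading bulk DC also led pDNA, although the plasmid pool was never in cells. Their pDNA reads above the median guide were a near-constant share of their reads in the other 5 libraries, with an SD of 0.0905 on the log2 scale, which is consistent with about 0.717% of the reads of the cell libraries having been counted as pDNA. The next 88 guides by bulk DC reads, which did not enter that estimate, had pDNA reads above the median guide by a mean log2 of 1.19 and above what this share predicts by 0.05 (SD 0.28). An excess in the plasmid pool passed on through the cells would have had to vary from 1.65 to 33.6 times the pDNA reads by day 11 (log2 SD 1.33). It would then have had to return to between 57.5 and 87.0 times in bulk DC (log2 SD 0.19). In 100000 shuffles of the change after day 11 this SD was at least 0.46. The guides were chosen by bulk DC reads, which by itself favours larger later rises of guides low on day 11, so the shuffles overstate the spread to be expected. With that limit, the values argue against such an excess as the whole cause unless later growth cancelled earlier growth, while a smaller excess stays open. Whether any such reads came from misread indexes or from material carried over was not tested, nor was a biological explanation.

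Guides that expanded up to bulk DC were picked for rising, so only their overlapping partners can test a shared effect. If loss of the targeted gene drove the rise, partners should rise by 1 log2 unit or more on average, but the partners of the 24 paired guides at least 4-fold higher in bulk DC than in pDNA, with the 0.717% share subtracted, had a mean of -0.25 (SE 0.257), below 1 though above the -0.65 of all paired guides (permutation p = 0.0939). An average shared rise of 1 log2 unit was thus not seen for these 24, which are few of the 3900 guides that rose as much. The bound of 1 assumes that both guides of a pair act about equally, so a smaller or uneven shared effect stays possible. Chance expansion of single clones also remains open and untested. For the 9 guides at least 8-fold higher the partners' mean was 0.53 (SE 0.392; exceeding random pairings with a permutation p of 0.0154), which leaves a shared effect possible.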

How the results depend on the processing

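Settings other than TMM factors, the pseudocount of 5, the filters and the reference libraries were chosen after seeing the data. No paired analysis was possible because each group had 1 library and the labels give no replicate numbers. Of the alternatives fixed beforehand, the other nulls of the rank test, the test of gene means, the removal of the strongest guide and those for gene lists were not run, since guides were not paired with genes. The cause was not tested unless stated.

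The correlation of overlapping guides in day 5 and day 11 against pDNA stayed past the threshold under each setting run. In all, 60 correlations kept their side of the threshold, 13 were no longer past it and 1 turned in sign. The 60 include those of sorted cells, which were not past it at the start. Of the counts of pairs higher in pDC, each adjusted over 14 counts, 7 kept their side and 4 did not. For guides lower, 46 counts stayed within 1.5 times and 14 did not, and the same numbers held for guides higher.

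A pseudocount of 5 shrinks changes of guides with few reads by construction. With it, guides lower and higher by 2-fold were 3711 and 78 for day 5 against pDNA, 6246 and 3473 for day 11 against pDNA, 458 and 1705 for day 11 against day 5, 1221 and 2141 for bulk DC, 631 and 503 for cDC2 and 730 and 1524 for pDC against bulk DC, and 3531 and 4938 for pDC against cDC2. The robust SD became 0.313, 0.564, 0.398, 0.426, 0.384, 0.415 and 0.572 in the same order. A pseudocount of 0.1 gave 400 guides higher on day 5, 9520 lower from day 5 to day 11, 9112 lower and 9259 higher in bulk DC, 15141 and 8344 in cDC2, and 16944 and 8957 in pDC. Against day 5, 12150 guides were higher in bulk DC, and the mean of the 3 day 18 libraries gave 7977 lower. Against day 11, cDC2 had 14332 lower and 9421 higher, and pDC 16316 and 13216.

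For bulk DC against day 11 the pair correlation was no longer past the threshold with TMM factors (0.067), a pseudocount of 0.1 (0.068), the filter at 50% (0.103), 6 to 14 G or C bases (0.103), opposite strands (0.112), at least 3 RPM in the reference (0.118), an overlap of at least 18 bases (0.051) or day 5 as reference (0.053). For day 11 against day 5 this held with a pseudocount of 5 (0.0050), the filter at 50% (0.108), opposite strands (0.117), 3 RPM (0.045) and an overlap of 18 (0.123). Opposite strands, the overlap of 18 and the 3 RPM leave fewer pairs. For cDC2 the sign turned against day 11 (0.104, adjusted permutation p = 0.0367), a comparison that includes the change up to bulk DC. The 8 pairs higher in pDC (1.95 in random pairings) became 1 (0.1002) with a pseudocount of 5, 2 (0.683) on opposite strands, 3 (0.722) with 3 RPM in the reference and 13 (10.2) against day 11, each short of the threshold. Few reads limit single guides in the sorted libraries, where the 10th percentile was 4 reads in cDC2 and 6 in pDC. The pDC library had more reads in total than either progenitor library, so this goes with uneven representation and not with sequencing depth alone.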

Other observations

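The tests and values in this part were all chosen after seeing the data.

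The log2 changes of cDC2 and of pDC, both against bulk DC, had a covariance of -0.0084 over guides (r = -0.015 across guides, which are not replicates), where 20 simulations of unchanged sorted libraries sharing the bulk DC library gave a mean of 0.0047 (0.0046 to 0.0049) from sampling of reads alone. The 315 guides whose partner was lost by day 5 had too few reads for the sort to be compared on the log2 scale, with medians of 0.445 RPM in bulk DC, 0.244 in cDC2 and 0.213 in pDC (27, 5 and 7 reads), where the other 591 paired guides had 4.44, 4.45 and 3.87.

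The sorts held 57.8 cells per guide for cDC2 and 37.7 for pDC on average, and 23.8 and 15.5 for a guide at the median of bulk DC. The variance among 13773 guides near that median, less the variance of reads, equals that of drawing 2.41 cells per guide for cDC2 and 2.10 for pDC, which is 9.87 and 7.39 times fewer than were sorted. These numbers also take in PCR, the amount of DNA used, reads counted in the wrong library and true effects of guides, which were not separated.

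Guides poor in G and C were lower on day 5. Among 751 guides with at most 5 G or C bases, which had a median of 557 pDNA reads, 23.2% were at least 2-fold lower on day 5 than in pDNA, against 8.54% of guides with 6 to 14. From day 5 to day 11 their median log2 change was -0.01.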
